A study of Homo sapiens with 18 samples.

How the data were processed

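Total RNA of HCT116, a human colon adenocarcinoma cell line, and of an isogenic derivative with p53 knocked out was measured on Illumina HumanHT-12 v4 BeadChips, per the labels. Each array carries bead-bound probes that bind labelled RNA, and the brightness of a probe stands for the level of its transcript. Per the labels, each genotype had 3 biological replicates with 3 technical arrays each, 18 arrays in all. Biological replicate 1 of both genotypes made up batch 1 (6 arrays), and replicates 2 and 3 of both made up batch 2 (12 arrays). The labels do not say how the biological replicates were grown, so the p-values measure the spread between these replicates only.

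The authors deposited 2 tables. The scanner table holds an average bead intensity per probe and array, with a detection p-value beside each, per the file headers. The intensities differed in their quantiles between arrays, so they were taken as not normalized. GenomeStudio 2011.1 and limma are named in the submitters' processing notes, which give no role for either. The second deposited table holds values on a natural log scale. Its scale and processing are not given in the sources used here and were settled from the values. Every column of it correlated best with the scanner intensities of its own array, in 18 of 18 arrays, and its sorted values followed the mean sorted natural log of the intensities without background correction. Every column of that table had a median of 5.05. It was used as an alternative only, after conversion to log2.

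The scanner intensities were corrected for background and quantile normalized with neqc in limma 3.58.1 under R 4.3.3, with the background estimated from the detection p-values and an offset of 16 added before log2. Of 47322 probes, 17849 were kept because their detection p was under 0.05 on at least 2 of 3 technical arrays in at least 3 of the 6 biological replicates. Probe names in the scanner table are those of the array's design. They were brought to current symbols with a RefSeq gene table (assembly GRCh38.p14, used for names and gene order only): 27041 probe names were current symbols, 4625 matched 1 older symbol, 3486 matched a gene number, 12116 had no match and kept the name in the file, and 54 had been turned into dates and were carried under their probe identifier. Where several probes stood for a gene, the probe with the highest mean over all 18 arrays was used, which left 14124 genes. Among 214 changed genes with more than 1 kept probe, 2 had probes called in opposite directions and 26 had a probe of opposite sign.

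The 3 technical arrays of a replicate were averaged, so that n was 3 per genotype. A linear model with genotype and batch was fitted per gene with lmFit and eBayes in limma, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05. Fold changes are p53 knockout minus parental on the log2 scale. Where a probe was detected on none of the 9 arrays of a genotype, the ratio is given as "at least N-fold": the bright genotype's mean was set against the dim genotype's mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Such a bound holds only for intensities with this background correction. Where it was detected on 1 to 3 of the 9 arrays, the ratio computed in the same way is given as a fold with the arrays raised to the floor. SDs are over the 3 replicate means of a genotype.

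The 20 gene lists were fixed before the data were examined and were tested with camera in limma at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Lists with at least 2 measured members, 19 of the 20, were tested and adjusted together. Markers of fibroblasts, endothelium and blood were among them. The genes named in the text were chosen by a rule set beforehand: CDKN1A and MDM2, the 12 largest increases and 12 largest decreases that kept their sign in each pair of replicates with the same number, and up to 4 changed members per list with the largest change, or the member with the smallest p where none changed. Any other gene was named after its values were seen, as said beside it. Some results that this rule selects are not reported here.

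Replicate numbers were checked for pairing. The deviations of replicates with the same number from their genotype means correlated across genes at 0.207, 0.135 and 0.157 for replicates 1, 2 and 3. All 3 were above the bound of 0.1 set beforehand, so the numbers may pair the samples, by the values rather than by the labels. The main fit kept the batch term and did not use this pairing. Replicates with the same number also share a batch, and the batch was not removed from the deviations. The correlations therefore cannot tell pairing from a shared batch. A fit with the replicate number as a block in place of the batch was run as an alternative.

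On simulated data with the measured means, spreads and batch, 200 of 14124 genes were changed by known folds in each of 5 runs. The fit called 96.4% of genes changed 4-fold, 40.3% of those changed 2-fold and 2.4% of those changed 1.5-fold, and 7.4% of its calls were false on average. In 5 of 5 runs camera called a list shifted 1.3-fold, and it called 0 other lists. For each gene the simulated noise had the same spread in every replicate, whereas parental replicate 2 stood apart in the data. The shares of genes called and of false calls therefore need not hold for the data. The noise was also drawn independently for every gene, so these runs do not show how the list test acts where members vary together. In the data the estimated correlation of members was 0.329 for p53-activated and 0.851 for G2/M genes, but -0.00527 for cholesterol synthesis genes.

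Arrays gave median intensities between 118.5 and 179.1 and detected between 16341 and 19029 probes, which was 34.5 to 40.2% of all probes. No array column was identical to another. The number of arrays limits the precision of all values. Alternatives covered the batch term, the replicate block, the treatment of technical arrays, background correction, normalization, the deposited natural log table, the filter on dim probes, the choice of probe, the eBayes prior, the threshold, batch 2 alone, and each replicate left out in turn. Array weights were added as an alternative after seeing the data.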

Results

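Gene expression was compared between parental HCT116 cells, a human colon adenocarcinoma line, and an isogenic derivative in which p53 had been knocked out. Levels were read on 18 bead arrays, with 9 arrays per genotype from 3 biological replicates of 3 technical arrays each. Between 16576 and 19029 probes were detected on the knockout arrays and between 16341 and 18625 on the parental arrays. Replicate means of the knockout correlated with each other across genes at r = 0.990 to 0.996. Parental replicates 1 and 3 correlated at r = 0.991, whereas parental replicate 2 reached only r = 0.946 with replicate 1 and r = 0.952 with replicate 3. These correlations are across genes, which are not independent replicates. The 3 technical arrays of parental replicate 2 lay together and detected 17920 to 18625 probes. Because this replicate stood apart, some values are also given without it.

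**Figure D1:**
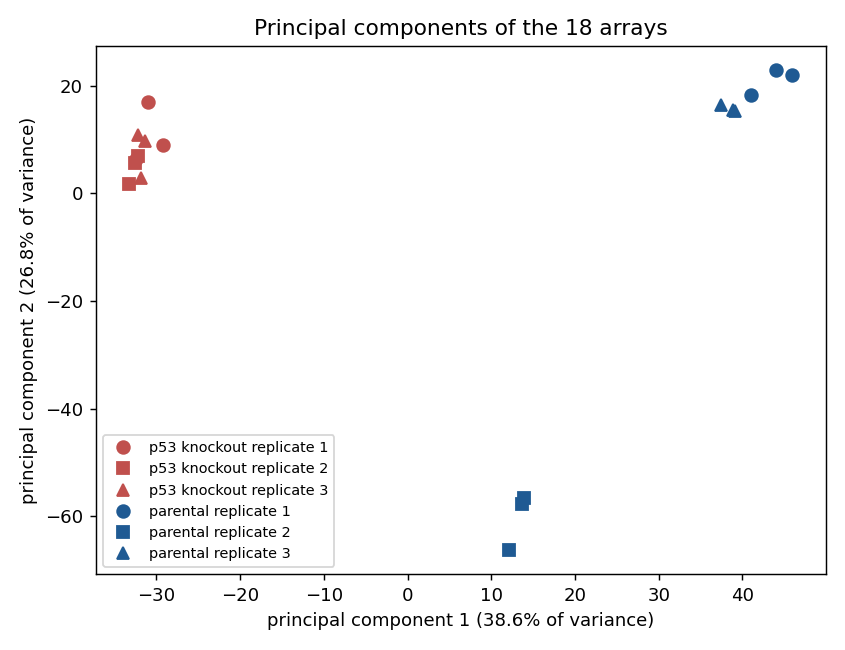
Principal components of the 18 arrays over 14124 genes; each point is an array, colour marks the genotype and shape the biological replicate, and the axes carry 38.6% and 26.8% of the variance. Knockout arrays lie on the left, and the 3 arrays of parental replicate 2 lie apart from the other parental arrays on the second axis.

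Which transcripts differ between the lines was asked first for CDKN1A and MDM2, genes that p53 is known to activate. Neither passed the threshold with all replicates. CDKN1A, which encodes the cell cycle inhibitor p21, read 11.78 ± 0.17 (SD, n = 3) in the knockout and 12.79 ± 1.28 (SD, n = 3) in the parental line (log2 fold change -1.02, SE 0.57, limma adjusted p = 0.353). The parental replicates read 13.52, 11.32 and 13.54, so that replicate 2 lay below the knockout mean. A dimmer CDKN1A probe, which the filter removed, was detected on 0 of 9 knockout and 6 of 9 parental arrays, and there parental replicate 2 read 5.33, above the knockout replicates (4.73 to 4.94) and below the other parental replicates (6.21 and 6.49). The log2 fold change of CDKN1A was -1.73 without parental replicate 2 (limma adjusted p = 0.000473), -0.46 without parental replicate 3 (adjusted p = 0.6) and -0.74 without parental replicate 1 or knockout replicate 1 (adjusted p = 0.729). MDM2, the ubiquitin ligase that p53 induces, gave a log2 fold change of -0.03 (SE 0.22, limma adjusted p = 0.96), and 3 of its 4 probes were detected on no array. The probe used was detected on 8 of 9 knockout and 5 of 9 parental arrays. Its means, 5.66 in the knockout and 5.69 in the parental line, lay near the lowest value of a detected probe. That floor was 5.41 to 5.68 across arrays, so a change in MDM2 could be missed.

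**Figure D2:**
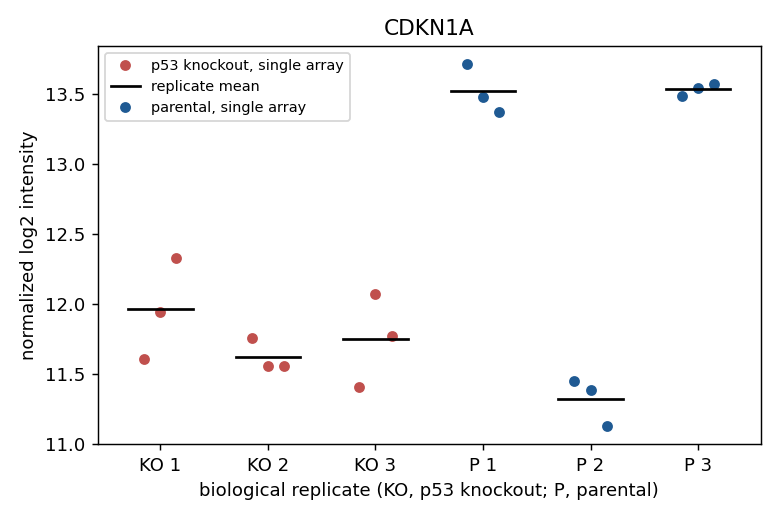
Normalized log2 intensity of CDKN1A on each array; points are technical arrays, bars are means of the 3 arrays of a biological replicate, and KO and P mark p53 knockout and parental. Parental replicate 2 (11.32) lies below the knockout mean of 11.78, and parental replicates 1 and 3 lie at 13.52 and 13.54.

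Across 14124 genes, 876 changed, of which 489 were higher and 387 lower in the knockout. The change was at least 2-fold in 298 of the higher and 241 of the lower genes. All 876 had the same sign in both batches and in all 3 pairs of replicates with the same number. The genes were called from these same replicates, so that agreement is no separate support. The labels name no separate knockout clones, so genotype and cell line coincide. The loss of p53 therefore cannot be told apart from other differences between the lines. WDR72, which encodes a WD-repeat protein, was at least 28.5-fold higher in the knockout, where it was detected on 9 of 9 arrays, against none of the parental arrays. TMEM200A was at least 31.3-fold higher, RAB40B at least 16.1-fold, PLAC8 at least 15.4-fold and ZNF83, a zinc finger gene, at least 12.3-fold. The Rab GTPase gene RAB34 was at least 9.1-fold higher, ZBED2 at least 7.7-fold and LZTFL1 at least 6.4-fold. These 8 genes were undetected on all 9 parental arrays. CRIP1, a LIM-domain gene, rose by a log2 fold change of 4.89 (SE 0.37), SFTA1P by 3.71 (SE 0.28), and EMP1 by 3.61 (SE 0.16). CRIP1 was detected on 6 and SFTA1P on 5 of 9 parental arrays. The small nucleolar RNA gene SNORA31, detected on 2 of 9 parental arrays, was 9.4-fold higher with the parental arrays raised to the detection floor where they lay below it. The limma adjusted p of the 12 largest fitted increases lay between 0.000152 and 0.00258.

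Of the 12 largest fitted decreases, 7 were in genes undetected on all 9 knockout arrays. A transcript known only by the cluster name HS.543887 was at least 46.0-fold lower in the knockout, and the scavenger receptor gene CD163L1 at least 30.95-fold lower. PROM1, which encodes the surface antigen CD133, was at least 19.1-fold lower, DPYSL3 at least 16.3-fold, MLPH at least 15.8-fold, the folate enzyme gene ALDH1L1 at least 13.6-fold and the adhesion receptor gene ADGRF1 at least 12.9-fold. TNFRSF6B, a decoy receptor of the TNF receptor family, was detected on 6 of 9 knockout arrays. It gave a log2 fold change of -5.27 (SE 0.61), BMS1P9 -4.38 (SE 0.80) and LOC644322 -4.23 (SE 0.70). These 3 gave -6.03, -5.41 and -5.12 without parental replicate 2. The call of BMS1P9 was lost without any 1 of the other 5 replicates (-3.63 to -4.57, limma adjusted p = 0.0584 to 0.225). TNFRSF6B and LOC644322 lost theirs without any 1 of knockout replicates 1 to 3 or parental replicate 1. Their limma adjusted p were then 0.0664 to 0.0918 and 0.143 to 0.19. NETO2 and HERC5, detected on 1 and 2 of 9 knockout arrays, were 15.4-fold and 17.1-fold lower with the knockout arrays raised to the floor. The limma adjusted p of these 12 decreases lay between 0.000152 and 0.0364. In 6 of these 24 genes (CRIP1, HS.543887, PROM1, TNFRSF6B, BMS1P9 and LOC644322), parental replicate 2 differed from the mean of the other parental replicates by more than 1 on the log2 scale.

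All these folds rest on the background correction. Without it all 72 named genes had smaller folds, 49 of them by over 1.5 times, and that of WDR72 fell from a fitted 5.79 to 3.41 on the log2 scale. Of the 22 named genes with an "at least" fold, 21 lay below that fold without the correction.

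The number of changed genes moved with each replicate that was left out. It was 5489 without parental replicate 2 (2816 higher, 2673 lower), and all 876 genes were among them with the same sign. It was 120 without knockout replicate 1 or without parental replicate 1, 82 without knockout replicate 2, 108 without knockout replicate 3 and 507 without parental replicate 3. Of 72 named genes, 68 had a call. Of these, 38 to 41 lost it when any 1 of knockout replicates 1 to 3 or parental replicate 1 was left out. The call was lost in 20 without parental replicate 3 and in 0 without parental replicate 2. Batch 1 holds 1 replicate per genotype and allows no test by itself, and batch 2 by itself gave 120 genes.

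**Figure D3:**
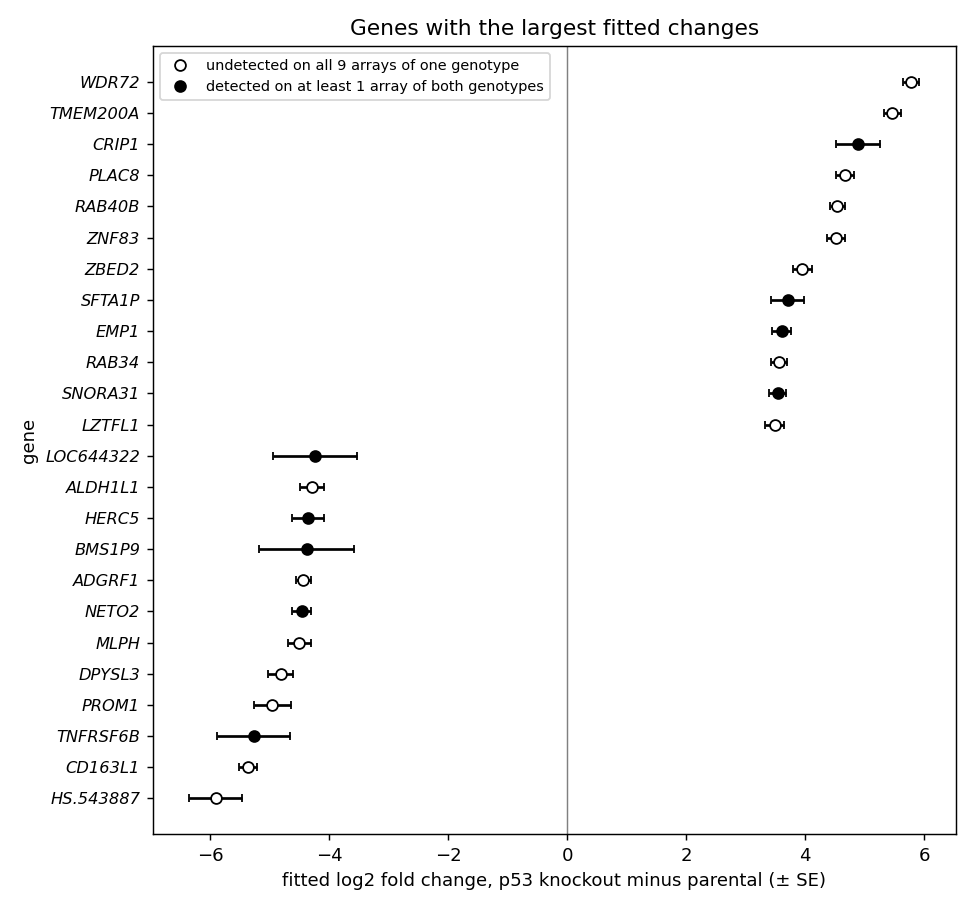
Fitted log2 fold change (p53 knockout minus parental) with its SE for the 12 largest increases and 12 largest decreases. Open points mark genes undetected on all 9 arrays of one genotype, for which the fitted value is not a bound, so that their order is not one of fold. Fitted values run from -5.90 to 5.79.

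The list of genes that p53 is known to activate passed downward in camera with the preset correlation (adjusted p = 0.000319), but passed neither with an estimated correlation (adjusted p = 0.997) nor in fry (adjusted p = 0.364). Of 107 measured members, 11 fell, 3 rose and 93 did not pass the test, and adjusted over the list alone 17 fell and 3 rose. DDB2, a DNA damage recognition factor detected on 2 of 9 knockout arrays, was 4.7-fold lower with the knockout arrays raised to the floor (limma adjusted p = 0.00301). RINL, detected on 4 of 9 knockout arrays, fell by 2.46 on the log2 scale (SE 0.34, limma adjusted p = 0.0161). TP53I3, a quinone oxidoreductase gene, was at least 3.3-fold lower (limma adjusted p = 0.0029), as was the death receptor gene FAS (limma adjusted p = 0.0195). The 3 members that rose, named after their values were seen, were ZFP36L1 at 2.25, MR1 at 1.49 and FAM210B at 1.33 on the log2 scale. The parental mean of MR1, 5.30, lay below the detection floor of 5.41 to 5.68 across arrays, so its fold is uncertain. The median log2 fold change of the list was -0.28, with -0.45 in batch 1 and -0.24 in batch 2. In parental replicate 2 the list lay 0.66 below the mean of the other parental replicates (median over members, log2), and 79 of the 107 members were lower there than in both others. Without that replicate 62 members fell and 6 rose.

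Regulators of apoptosis did not pass the list test. Of 38 measured members, 3 fell, 2 rose and 33 did not pass, with 5 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.993). CASP4, an inflammatory caspase gene detected on 6 of 9 knockout arrays, fell by 2.83 (SE 0.53, limma adjusted p = 0.0387), or by 3.49 without parental replicate 2. The pro-apoptotic gene BAX fell by 1.28 (SE 0.20, limma adjusted p = 0.0236), beside FAS. BCL2, which encodes an inhibitor of apoptosis and was detected on 5 of 9 parental arrays, rose by 1.03 (SE 0.18, limma adjusted p = 0.0318). Its limma adjusted p was 0.0506 with the replicate block. CASP8, named after its value was seen, rose by 0.86 (limma adjusted p = 0.0486, and 0.0614 with the replicate block). The parental mean of CASP8, 5.53, lay within the detection floor of 5.41 to 5.68 across arrays. The median of the list was 0.08 and its mean -0.09, so that they differed in sign, and the direction of camera followed the median. With parental replicate 2 left out, 6 members rose and 9 fell.

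The list of interferon-stimulated genes passed downward in camera with the preset correlation (adjusted p = 0.00722), but not with an estimated correlation (adjusted p = 0.997), in fry (adjusted p = 0.432) or without parental replicate 3 (camera adjusted p = 0.212). Of 39 measured interferon-stimulated genes, 5 fell, 0 rose and 34 did not pass, and adjusted over the list alone 10 fell and 1 rose. HERC5, the ligase for the ubiquitin-like modifier ISG15, is given above. PARP9 was at least 2.6-fold lower (limma adjusted p = 0.026), IFITM2 fell by 1.73 (SE 0.29, limma adjusted p = 0.0286) and OAS3 fell by 1.05 (SE 0.17, limma adjusted p = 0.0261). The fifth, TRIM21, named after its value was seen, fell by 0.76 (limma adjusted p = 0.0274, and 0.0531 with the replicate block). The list had a median of -0.28 (-0.71 in batch 1 and -0.26 in batch 2). In parental replicate 2 its median lay 1.13 below the other parental replicates, with 34 of 39 members lower than in both. Without that replicate 24 members fell and 2 rose, and the median was -0.69.

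The list of cholesterol synthesis genes passed downward in camera with the preset correlation (adjusted p = 0.00121) and in fry (adjusted p = 0.00625), but not with an estimated correlation (adjusted p = 0.355). Of 31 measured members, 6 fell, 0 rose and 25 did not pass, and adjusted over the list alone 10 fell and 2 rose. INSIG1, which encodes a sterol sensor partner, fell by 1.38 (SE 0.15, limma adjusted p = 0.00896) and the mevalonate kinase gene MVK, detected on 1 of 9 knockout arrays, was 1.46-fold lower with the knockout arrays raised to the floor (limma adjusted p = 0.0399). DHCR7 fell by 0.86 (SE 0.18, limma adjusted p = 0.0492) and IDI1 fell by 0.82 (SE 0.15, limma adjusted p = 0.0372), and with the replicate block their adjusted p were 0.0717 and 0.0625. The median was -0.36, with -0.42 in batch 1 and -0.35 in batch 2. In parental replicate 2, 15 of the 31 members were higher than in both other parental replicates and 13 lower than in both (median difference 0.01), and 17 members fell and 5 rose without that replicate.

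3 lists passed upward in camera with the preset correlation, and none of them with an estimated correlation. For the list of the NRF2 response and of iron or glutathione handling, the camera adjusted p = 0.00845 became 0.355 with the estimated correlation, and fry gave an adjusted p = 0.000689. Of 32 measured members, 3 rose, 1 fell and 28 did not pass, and the counts adjusted over the list alone were the same 3 and 1. NQO1, a quinone reductase gene, rose by 2.07 (SE 0.17, limma adjusted p = 0.00306). The cystine transporter gene SLC7A11, undetected on all 9 parental arrays, was at least 1.05-fold higher (limma adjusted p = 0.0405), and its adjusted p was 0.0602 with the replicate block. The export pump gene ABCC2, detected on 6 of 9 knockout arrays, fell by 1.25 (SE 0.19, limma adjusted p = 0.0217). The median was 0.38, or 0.30 with undetected members at their bounds, and 0.27 in batch 1 and 0.28 in batch 2. In the fit that left out parental replicate 2, 15 members rose and 4 fell.

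The list of the ATF4 and unfolded protein response had a camera adjusted p = 0.0208, but 0.997 with an estimated correlation, 0.432 in fry, 0.803 without parental replicate 2 and 0.0885 without the 6 members that another list also held. Of 38 measured members, 6 rose, 0 fell and 32 did not pass, and adjusted over the list alone 6 rose and 2 fell. CTH, which makes cysteine, rose by 3.04 (SE 0.17, limma adjusted p = 0.00118). The serine synthesis genes PSPH and PHGDH rose by 1.66 (SE 0.34, limma adjusted p = 0.0468) and 1.48 (SE 0.26, limma adjusted p = 0.0332), and the tryptophanyl-tRNA synthetase gene WARS1 by 1.34 (SE 0.18, limma adjusted p = 0.0146). The median of the list was 0.55, but 0.03 in batch 1 and 0.70 in batch 2, and 0.46 with undetected members at their bounds. In parental replicate 2 the list lay 1.14 below the other parental replicates, with 32 of 38 members lower than in both. Without that replicate 14 members rose and 11 fell, and the median was 0.04.

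Only 12 of 42 cancer-testis genes, which are normally limited to the germ line, were measured. Of these, 3 rose, 0 fell and 9 did not pass, with the same counts adjusted over the list alone. PRAME was at least 5.4-fold higher (limma adjusted p = 0.000848). TEX14, detected on 3 of 9 parental arrays, was 3.4-fold higher with the parental arrays raised to the floor (limma adjusted p = 0.00755). MAGEC2, detected on 6 of 9 parental arrays, rose by 1.56 (SE 0.13, limma adjusted p = 0.00308). The median was 0.14, with 0.11 in batch 1 and 0.20 in batch 2. Camera gave an adjusted p = 0.0265, fry an adjusted p = 0.0112, and camera an adjusted p = 0.652 with an estimated correlation. The camera adjusted p was 0.0767 with no filter on dim probes, 0.0882 without knockout replicate 2, 0.093 without parental replicate 2 and 0.0507 without parental replicate 3, where the median was 0.07. Of the 10 ways to split the 6 replicates into 3 and 3, the genotypes included, 9 gave 6 or more lists past the threshold with the preset correlation.

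**Figure D4:**
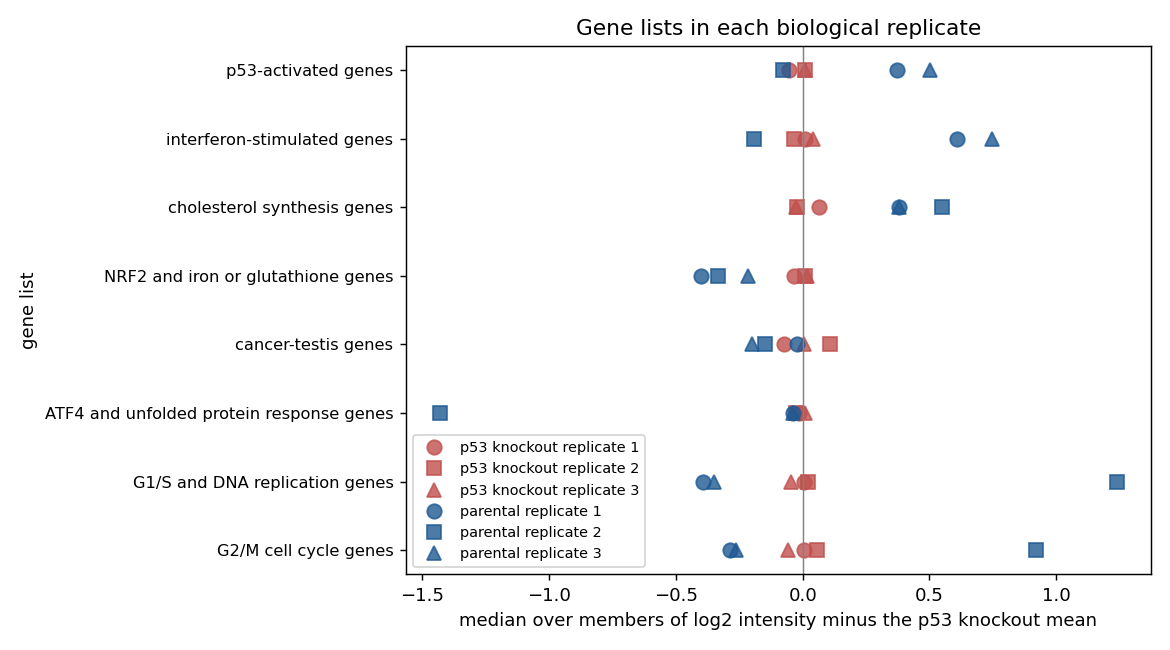
Median over list members of the log2 intensity minus the knockout mean of the same gene, for 8 lists (rows) in each biological replicate; colour marks the genotype and shape the replicate number. Parental replicate 2 (squares) lies near or below the knockout for the p53-activated, interferon-stimulated and ATF4 lists and above all others, at 1.24 and 0.92, for the lists of G1/S and G2/M genes.

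Cell cycle genes did not pass the list test with all replicates, and their direction depended on the replicates used. Of 64 measured G2/M genes, 1 rose, 0 fell and 63 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.586). The one that rose was CDC25C, a phosphatase gene of mitotic entry, by 1.02 (SE 0.16, limma adjusted p = 0.023). Of 56 measured genes of G1/S and DNA replication, 0 changed in limma at the adjusted threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.161). MSH6, the member with the smallest p, gave a log2 fold change of -1.23 (SE 0.30, limma adjusted p = 0.0744). The medians were -0.10 for G2/M (0.32 in batch 1, -0.33 in batch 2) and -0.13 for G1/S (0.37 in batch 1, -0.40 in batch 2). In parental replicate 2 the lists lay 1.32 and 1.61 above the other parental replicates, with 61 of 64 and 53 of 56 members higher than in both. Without that replicate 25 G2/M genes rose and 2 fell, and 28 G1/S genes rose and 4 fell, with camera adjusted p of 9.48e-05 and 0.000533 in the upward direction at the preset correlation, but 0.546 and 0.462 with an estimated correlation. The next values also come from the preset correlation. Without parental replicate 3 the medians were -0.38 and -0.48, with camera adjusted p of 0.000563 and 9.06e-05 downward. Without knockout replicate 1, or without parental replicate 1, they were -0.33 and -0.40, with camera adjusted p of 0.0129 and 0.00165 downward.

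Genes of MAPK signalling and the early response gave a camera adjusted p = 0.0541, with 0.997 at an estimated correlation and 0.478 in fry. At the preset correlation it was 0.0476 with the replicate block, 0.0165 with no filter on dim probes and 0.0341 without members that another list also held. Of 33 measured members, 2 rose and 1 fell, with 4 and 1 adjusted over the list alone. The phosphatase gene DUSP4 was at least 3.0-fold higher (limma adjusted p = 0.00242), ETV5 rose by 1.26 (SE 0.19, limma adjusted p = 0.0219), and the growth factor gene EREG fell by 2.10 (SE 0.32, limma adjusted p = 0.0211). The list median was 0.15 (-0.13 in batch 1, 0.46 in batch 2), and in parental replicate 2 the list lay 0.74 below the other parental replicates. Its camera adjusted p at the preset correlation was 0.00719 without knockout replicate 1 or parental replicate 1 and 0.000459 without parental replicate 3, whereas without parental replicate 2 the median was -0.20 (camera adjusted p = 0.346), with 8 members higher and 12 lower. Of 49 measured DNA repair genes, 2 rose and 2 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.946; median 0.02, mean -0.01, camera direction downward). The end-joining ligase gene LIG4, detected on 4 of 9 parental arrays, was 2.46-fold higher (limma adjusted p = 0.00946). FANCL rose by 0.95 (SE 0.15, limma adjusted p = 0.0251), while NBN fell by 0.70 (SE 0.14, limma adjusted p = 0.0422), as did DDB2. The adjusted p of NBN was 0.0696 with the replicate block. The DNA repair list lay 0.62 higher in parental replicate 2 than in the other parental replicates, and without that replicate 22 members rose and 8 fell, with a median of 0.31 and the camera direction upward (adjusted p = 0.0813).

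Epithelial and mesenchymal genes changed singly. Of 20 measured epithelial and intestinal genes, 1 rose and 2 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.847; median 0.09, mean -0.07). The keratin gene KRT19 fell by 2.52 (SE 0.15, limma adjusted p = 0.00145), the tight junction gene CLDN3 was at least 2.0-fold lower (limma adjusted p = 0.0219), and the epithelial transcription factor gene GRHL2 rose by 0.92 (SE 0.15, limma adjusted p = 0.028). Of 19 measured mesenchymal genes, 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.83; median 0.36, mean 0.01). The actin gene ACTA2 fell by 3.03 (SE 0.60, limma adjusted p = 0.0446) and the transcription factor gene TWIST1, detected on 1 of 9 knockout arrays, was 4.0-fold lower with the knockout arrays raised to the floor (limma adjusted p = 0.0022). The mesenchymal list lay 0.66 lower in parental replicate 2 than in the other parental replicates. Without that replicate its median was 0.06, with 7 members higher and 5 lower, and epithelial and intestinal genes gave 5 higher and 7 lower. ACTA2 read 7.61 in parental replicate 2 against 9.85 and 9.74 in the other parental replicates, so that it fell by 3.79 without it.

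Metabolic, ribosomal and WNT target genes did not pass the list test with all replicates. Of 36 measured genes of glycolysis and hypoxia, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.847; median -0.03, mean 0.04). ENO2 rose by 0.73 (SE 0.13, limma adjusted p = 0.0346, and 0.063 with the replicate block) and the lactate exporter gene SLC16A3 fell by 1.19 (SE 0.16, limma adjusted p = 0.0156). Without parental replicate 2, 12 rose and 9 fell. Of 56 measured genes of oxidative phosphorylation, 1 rose, CYC1 by 1.23 (SE 0.20, limma adjusted p = 0.026), and 0 rose adjusted over the list alone (camera adjusted p = 0.847, and without parental replicate 2 it was 0.0115 upward, or 0.646 with an estimated correlation). Without that replicate 13 members rose and 1 fell, and in it the list lay 0.44 higher than in the other parental replicates. Of 75 measured ribosomal protein genes, 1 rose, RPL28 by 1.22 (SE 0.19, limma adjusted p = 0.0231), and 0 rose adjusted over the list alone (camera adjusted p = 0.993; median 0.01, mean -0.00). When parental replicate 2 was left out, 2 rose and 9 fell. Of 16 measured WNT target genes, 0 rose and 2 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.946). FGF9, detected on 2 of 9 knockout arrays, was 1.91-fold lower with the knockout arrays raised to the floor (limma adjusted p = 0.0231) and NKD2 fell by 0.70 (SE 0.13, limma adjusted p = 0.0404, and 0.0688 with the replicate block). The counts were 3 and 4 when parental replicate 2 was left out.

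Few markers of other cell types were measured. Of 14 fibroblast markers 2 were measured, and COL1A1, a collagen gene, rose by 1.08 (SE 0.16, limma adjusted p = 0.0181). Of 11 endothelial markers 1 was measured, ESAM, with a log2 fold change of 0.19 (SE 0.23, limma adjusted p = 0.7). Of 16 blood markers 3 were measured, and the haemoglobin gene HBA2, detected on 6 of 9 knockout arrays, fell by 1.70 (SE 0.18, limma adjusted p = 0.00796). Adjusted over the list alone, 1 fibroblast marker rose and 2 blood markers fell. The camera adjusted p was 0.237 for the fibroblast list and 0.102 for the blood list. The blood list had a median of -0.86, or -0.37 with its undetected member at its bound. In parental replicate 2 both measured fibroblast markers were lower than in the other parental replicates, with a median difference of -1.42 on the log2 scale. All 3 blood markers and ESAM were lower there too, with median differences of -0.67 and -0.61. Without that replicate the median log2 fold change of the fibroblast list was 0.06, against 0.56 with all replicates.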

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

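All values in this part were screened by a rule fixed before the data were examined. Over 75 quantities (72 named genes and 3 measures of array quality), each genotype's 9 arrays were searched for an array far from the other 8, and 8 of the 150 groups had one. With independent arrays, chance alone would flag about 1 in 20 groups. The 9 arrays include technical arrays and are not independent, so that rate need not hold and does not explain the 8. The rule seeks a single array, so it does not show whether a whole replicate stands apart.

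In the parental line, ESAM read 5.00 on array 3 of replicate 2 against 6.25 on the nearest array. LZTFL1 read 5.22 on the same array, the highest of the 9, against 4.82, and FANCL read 8.47 on array 1 of replicate 2 against 8.05. GRHL2 read 5.43 on array 2 of replicate 1 against 6.03, and PRAME read 5.28 on array 1 of replicate 1 against 5.01, both in the parental line. In the knockout, DUSP4 read 6.32 on array 3 of replicate 1 against 6.91, OAS3 read 6.89 on array 3 of replicate 3 against 6.32, and TWIST1 read 5.86 on array 3 of replicate 2 against 5.16. All are log2 intensities.

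The genotype split was set against the other splits of the 6 replicates into 3 and 3. It gave 876 changed genes in limma (3303 at an unadjusted p under 0.05). The highest of the other splits gave 23 changed genes, and the highest at an unadjusted p under 0.05 was 2515. Of the 10 splits, 1 reached 876. For the gene lists it gave 6 and the highest of the others gave 10, and 9 of the 10 splits gave 6 or more. With 10 splits no share under 0.05 can be reached. The 4 splits that part all 3 pairs, the genotypes included, gave 876 genes in limma against 0 in the others (at most 680 at an unadjusted p under 0.05), and 6 lists against 5 to 8.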

How the results depend on the processing

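Array weights were chosen after the data were seen, and all other alternatives were set before and were run. Among alternatives not named next, the counts of 489 higher and 387 lower genes stayed within 1.5 times, between 376 and 622 higher and 310 and 482 lower; the replicate block gave 376 and 310. Higher and lower counts were 1389 and 1072 with duplicateCorrelation over 18 arrays, and 2464 and 2144 with 18 arrays as independent samples, which counts technical arrays as replicates. They were 66 and 54 in batch 2 only, where fewer samples are left, and 121 and 110 at an adjusted p under 0.01. With array weights they were 3245 and 3154. The weights ran from 0.08 for parental replicate 2 to 6.95 for knockout replicate 3. Leaving out 1 replicate gave 42 to 2816 higher and 40 to 2673 lower; the highest came without parental replicate 2. Leaving out either replicate of batch 1 equals batch 2 only, since the batch term absorbs the lone replicate.

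The number of lists fell from 6 to 0 with an estimated correlation and to 3 with fry, and the cause was not tested. For the cholesterol synthesis and NRF2 lists the estimated correlation was -0.00527 and -0.0283, below the preset 0.01. Their unadjusted camera p still rose, from 0.000128 to 0.0222 and from 0.00178 to 0.0374. Correlated members thus do not account for the loss of both lists. The fit left 3 residual degrees of freedom, so a list that did not pass there is not shown to be unshifted. The number of lists was 5 to 9 with 1 replicate left out. It was 7 with the replicate block, which added MAPK and early response genes. With 1 replicate left out, the list medians spanned -0.38 to 0.28 for G2/M and -0.48 to 0.37 for G1/S, upward past the threshold only without parental replicate 2 (0.28 and 0.37, camera adjusted p = 9.48e-05 and 0.000533, but 0.546 and 0.462 with an estimated correlation); G2/M was also 0.02 without knockout replicate 3. Of 72 named genes, none changed sign where either fit called it. Of the 68 named genes with a call, 12 lost it without background correction and 12 in the deposited natural log table. The call was lost in 9 with no filter, 7 with the replicate block, and 0 to 41 with 1 replicate left out. BMS1P9 lost its call without background correction, in the deposited table, with no filter and without any 1 replicate other than parental replicate 2 (limma adjusted p = 0.0584 to 0.225 in the last); LOC644322 gave -3.56 without parental replicate 3. The replicate block changed no call of a gene or list in the text other than those given beside it. Without background correction all 72 had smaller folds, 49 by over 1.5 times (WDR72 5.79 to 3.41, CD163L1 -5.37 to -3.17, DDB2 -2.49 to -1.02), and 47 in the deposited table, since an uncorrected intensity carries the background in both genotypes. The list median of p53-activated genes moved from -0.28 to -0.14 without it, and that of interferon-stimulated genes to -0.17, or -0.12 with no filter. Signal over background thus limits the folds of dim probes.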

Other observations

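The genes and tests in this part were chosen after the data were seen, except the tests for genes detected in a single replicate and for the share of p53-activated genes, which were set before their results; the scan of neighbouring genes was set before, but how it was read was changed after. Metallothionein genes, which bind zinc and copper and lie side by side, were looked at singly, and no list of them was tested. MT1F gave a log2 fold change of -2.24 (limma adjusted p = 0.0096), MT1X -1.62 (limma adjusted p = 0.0447) and MT1IP -0.81 (limma adjusted p = 0.0286, and 0.0519 with the replicate block). MT2A, MT1E, MT1A and MT1G gave -0.57, -0.54, -0.56 and -0.73 and did not pass.

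Parental replicate 2 differed by at least 2-fold from the mean of parental replicates 1 and 3 in 1909 genes, 915 higher and 994 lower, whereas 116 genes differed by that much between replicates 1 and 3. A wholly mislabelled knockout culture is argued against by 59 genes at least 8-fold apart between the knockout and the other parental replicates. They were kept by a filter that did not use replicate 2. Of these, 45 (76.3%) were nearer the parental side in replicate 2 (19 of 20 higher and 26 of 39 lower in the knockout). Each knockout replicate, tested in the same way against the means of the others, had 0 of 54 to 62 such genes nearer that side. Parental replicates 1 and 3, each tested with the other as the parental side, had 100% of such genes nearer it. The share of replicate 2 lay between these, so the values argue only against a culture made up wholly of knockout cells. The share was first to reach 90%, and that bound was replaced, after the share was seen, by over 50% and above every knockout replicate. The array batch is argued against, since in 91.1% of 2118 genes that separated replicate 2 from replicate 1, replicate 3, of the same batch as replicate 2, was nearer replicate 1. A culture of another line or cell type is argued against by 0 genes detected only in replicate 2 and at least 4-fold above the detection floor, but 32 genes nearer the floor were detected only there, against at most 7 in any other replicate, so a small admixture stays open. The G1/S list lay 1.61 higher in replicate 2, against 0.17 at the upper end of the middle 95% of 10000 random lists matched on level, and the ATF4 list lay 1.14 lower. A culture with more DNA replication and less stress signalling is a hypothesis drawn from these same values, which therefore do not test it; no separate test was run, the labels describe no such difference and it stays open.

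Of the 62 p53-activated genes that fell without parental replicate 2, 42 lay nearer the knockout than the other parental replicates in replicate 2, CDKN1A, GDF15 and ATF3 among them, and 20 lay nearer the parental side, such as DDB2, SESN1, SFN and TP53I3. That share, 67.7%, was within the 46.8 to 71.0% that 10000 draws of other genes lower in the knockout gave, matched on fold. Of the 2611 other genes lower in the knockout, not matched on fold, 60.9% lay nearer the knockout. The test thus showed no difference between p53-activated and other genes. Its range is wide, so a difference within that range is not excluded. No biological explanation of the 20 was tested.

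Neighbouring genes were scanned in windows of 21 measured genes for shared shifts, as a difference in copy number between the lines could give, and 2 blocks passed the 95th percentile of the maximum over 1000 shuffles, with the same sign in all 3 pairs. LPAR5 to EMG1 held 21 genes with a median of 0.55, of which 18 were higher and 4 passed upward and 1 downward, and also passed without parental replicate 2 (median 0.61). BBS2 to DRC7, which contains the metallothionein genes, held 22 genes with a median of -0.49, of which 17 were lower and 3 passed downward and 1, CCDC102A, upward, and did not pass without that replicate. One block, CCNP to BCKDHA, passed between parental replicate 2 and the other parental replicates, where no copy number difference is named, so copy number and shared regulation cannot be told apart here. By the reading first set, blocks that kept their sign in all pairs would have counted for copy number; the comparison within the parental line was added after the 2 blocks were seen.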
